A study of Mus musculus with 5 samples.

How the data were processed

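The measurements were single-cell RNA sequencing of cells sorted from adult mouse brain and spinal cord. Per the labels' protocols, tissue of 3-month-old mice was dissociated, cells were sorted by fluorescence into 96-well plates, and each cell was made into its own library by Smart-seq2, a full-length cDNA method that carries no molecular identifiers. The labels gave 5 samples in 5 groups of 1 sample each. The samples of the Foxj1 line (an inducible Cre recombinase under the Foxj1 promoter with a tdTomato reporter) came from the lateral ventricle, the third ventricle, the midbrain aqueduct and the spinal cord. The sample of the Nkx2-2 line (Cre under Nkx2-2 with another reporter) came from the midbrain. Per the labels' protocols the Foxj1 line samples came from 10 animals, 5 females and 5 males, and the Nkx2-2 line sample from 7 females. No label tied a well to an animal.

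The authors deposited 2 tables with the same cells as columns. One held whole-number read counts per gene and cell, not normalized, as deposited. The other deposited table held log2 values. Its values equalled log2 of the count divided by 1 size factor per cell, plus 1, within 0.01 for 100% of them, and the size factors averaged 1, with a range of 0.0875 to 6.00. The method behind the size factors, the counting tool and the annotation were not given in the sources used here. STAR 2.3.1o, Seurat 3 and the mm10 build were named in the submitters' processing notes. The tables held 16347 gene names. Of these, 16028 matched a gene name of GENCODE vM21 on GRCm38, the assembly that mm10 also denotes, from which gene coordinates were taken, and 319 did not match.

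Columns were assigned to samples by the start of their names, with 0 columns left over. The name starts for midbrain, spinal cord and the Nkx2-2 line matched the sample titles directly. The name starts Forebrain and Tanycytes were taken as the lateral ventricle and the third ventricle, which rests on anatomy and on the titles of the other samples. Cell numbers were taken to follow the order of wells in the titles, so that the first 480 midbrain wells belonged to the first of 2 sequencing projects, which also held the other 3 regions. The second project held the remaining midbrain wells and the Nkx2-2 line.

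Cells needed at least 1000 detected genes and 20000 reads. All 1473 cells in the table met this, the shallowest with 108417 reads, so the filter removed no cell. No doublet caller was run, since each well was sorted to hold 1 cell. An alternative left out the 2% of cells with the most genes in each sample. Cells were clustered in scanpy 1.11.5 (counts scaled to 10000 per cell and log-transformed, 2000 highly variable genes without mitochondrial and sex-linked genes, 30 principal components, 15 neighbours, Leiden resolution 1 with igraph 0.11.9, no batch integration), which gave 18 clusters. Clusters were named from 15 marker sets fixed beforehand, and a name needed at least 3 detected markers. The 2 markers of the subcommissural organ were too few to name a class. Clusters with a mean log2 level of at least 8 for these 2 markers were set apart as Sspo-high, and other classes needed a mean of 5 for their markers. Both thresholds were chosen after the values were seen. The percent of cells that this threshold moved is given with the class shares. Against all other cells, clusters 6 and 17 each had 1 marker of another class and 0 of their own among their 10 leading genes, and cluster 13 had 2 and 0. Cluster 0, the largest Sspo-high cluster, had 3: Sspo and Spdef, the subcommissural organ markers that set this class apart, and Ttr, a choroid plexus marker. Clusters are therefore named by number beside the values. The lateral ventricle, third-ventricle and spinal cord samples entered their comparisons whole. The midbrain entered as its ependymal-like cells only, so the clustering bore on which genes were named. For example, the third-ventricle genes Lhfp and Nbl1 stood at 26.5 and 18.7 CPM in those midbrain cells. Among the cells left out, Lhfp stood at 164 CPM in cluster 0 and Nbl1 at 393 CPM in cluster 1.

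Raw counts were summed over the cells of a class in a sample and scaled to CPM, the usual normalisation of counts to a common total of reads in genes. With 1 sample per group there was no test between groups and no p-value. Each CPM has an exact Poisson 95% interval and each share of cells an exact Clopper-Pearson 95% interval. Reads without molecular identifiers are not independent molecules, so these intervals, and the floors used for a count of 0, cover counting error only. A fold against 0 reads was computed against a floor of 3 reads over the group and is given as a lower bound. Cells were not treated as replicates. Blocks of 96 consecutive cell numbers with at least 10 cells of a class described the spread within a sample, which holds differences between animals as well as technical ones, since sex-linked genes differed between blocks. The ependymal-like sums rested on 180906553 reads in the lateral ventricle, 203810153 in the third ventricle, 248083000 in the midbrain and 94640544 in the spinal cord.

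The following were chosen before the data were examined: the groups, the filters on cells, the size rule for named genes, 56 alternatives and 20 gene lists. The lists were Hox genes, forebrain patterning factors, hypothalamic patterning factors, midbrain and isthmus patterning factors, floor plate and dopamine progenitor genes, dopamine neuron genes, ventral patterning and hedgehog response genes, dorsal patterning genes, SOX and NFI factors, multiciliogenesis regulators, motile cilium components, radial glia and stem cell genes, BMP pathway genes, Wnt pathway genes, guidance and secreted cues, channels with transporters and junctions, interferon and antigen presentation genes, immediate early and dissociation response genes, cell cycle genes, and sex-linked genes. Of 260 fixed list genes, 220 were in the table. A list member counted where it reached 10 CPM in a compared sample. Each of 19 lists was summarised by the median log2 ratio of its members on the CPM + 1 scale, which understates changes of low genes, and by the percentile of that median among 10000 random lists of the same size drawn within 20 bins of mean expression. The percentile describes these libraries only. Sex-linked genes were reported by sample. Values of some single genes are not reported here.

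Beyond the lists, a gene was named where it had at least 50 CPM in the higher sample, a read in at least 25% of its cells of the class, a fold of at least 4, and blocks that did not overlap with those of the compared samples. At most 6 genes were named per region against the highest other region, and 10 per direction for the midbrain against the mean of the other 3 regions and for the 2 Cre lines within a class. Mitochondrial, ribosomal protein, predicted and sex-linked genes and transgenes were left out. For the 2 Cre lines, the 10 leading genes of the compared clusters were also left out, a choice made after the values were seen. The code of the rule was tested on simulated data with counting error only, which does not show how the rule behaves with the spread between blocks or animals. Counts for 16347 genes were drawn for every region from the same profile, the summed reads of all Foxj1 line midbrain cells, at each region's depth. In the midbrain draw, 50 genes were changed by each of 4 fold sizes. With the same profile in every region, unchanged genes differed little beyond counting error, so the rule could hardly find any of them. The rule found 0 of 50 genes changed 2-fold and 50 of 50 at each of 6-fold, 8-fold and 16-fold, with measured median log2 changes of 0.66, 2.24, 2.66 and 3.66 against simulated 0.67, 2.25, 2.67 and 3.67, and 0 unchanged genes. The simulated values lie below the folds because the changed genes took part of a fixed total. A simulated list of 10 changed genes lay at percentile 100 and an unchanged list at 52.1.

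The alternatives covered the filter on cells, the clustering settings, the way reads were combined over cells, the scaling (including TMM factors from edgeR 4.0.16 in R 4.3.3), the pseudocount, the list minimum, the region used as reference, thinning of each cell to 20000 reads, the sequencing project and leaving out each block. A further 5 alternatives were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The midbrain samples of the 2 Cre lines differed in line, reporter and make-up by sex, which could not be told apart. The Foxj1 line midbrain sample was split over both sequencing projects, so medians against its cells of the second project alone are given where they moved.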

Results

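Single cells were profiled from the walls of the ventricular system of adult mice, the fluid-filled cavities lined by ependymal cells, whose beating cilia move the cerebrospinal fluid. The series asked how the transcription factor Sox9 and the NFI factors time neurogenesis and ependymal maturation of dopamine progenitors. Cells labelled through the Foxj1 promoter, which is active in cells with motile cilia, were sorted from 4 places along the neuraxis. Cells labelled through Nkx2-2, a factor of the ventral neural tube, were sorted from the midbrain. Each of the 5 groups held 1 sample. The lateral ventricle sample held 240 cells from 288 wells (83.3%, 95% interval 78.5 to 87.4), with a median of 715589 reads per cell and 180906553 reads in all. The third-ventricle sample held 245 cells from 288 wells (85.1%, 80.4 to 89.0), with a median of 734669 reads and 203810153 in all. The Foxj1 line midbrain sample held 547 cells from 672 wells (81.4%, 78.2 to 84.3), with a median of 696997 reads and 439995813 in all. The spinal cord sample held 114 cells from 144 wells (79.2%, 71.6 to 85.5), with a median of 759184 reads and 94640544 in all. The Nkx2-2 line midbrain sample held 327 cells from 432 wells (75.7%, 71.4 to 79.7), with a median of 1.18e+06 reads and 431209063 in all. Median detected genes per cell ran from 3979.5 in the spinal cord to 5435.5 in the lateral ventricle. With 1 sample per group, no difference between groups could be set against replicate error, and all values describe these samples.

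The first comparison asked which cells each line and region gave. All 240 lateral ventricle cells (95% interval 98.5 to 100%) were ependymal-like, with markers such as Foxj1, Tmem212 and Rarres2. So were all 245 third-ventricle cells (98.5 to 100%) and all 114 spinal cord cells (96.8 to 100%). In the Foxj1 line midbrain sample, 305 of 547 cells were ependymal-like (55.8%, 51.5 to 60.0) and 30 were astrocyte-like (5.48%, 3.73 to 7.74). A further 212 cells had high Sspo (38.8%, 34.7 to 43.0), the gene of SCO-spondin, a large glycoprotein secreted into the cerebrospinal fluid. The Nkx2-2 line midbrain sample was mostly oligodendrocyte-like, with 247 of 327 cells (75.5%, 70.5 to 80.1). It also held 30 cells like oligodendrocyte precursors (9.17%, 6.28 to 12.8) and 21 astrocyte-like cells (6.42%, 4.02 to 9.65). Its ependymal-like cells numbered 18 (5.50%, 3.29 to 8.56) and its Sspo-high cells 11 (3.36%, 1.69 to 5.94). No oligodendrocyte-like or precursor-like cell was seen in the Foxj1 line midbrain sample, where 3 cells, the floor used for a count of 0, make 0.548% and the 95% interval reaches 0.672%. These are shares of sorted cells, so the Cre line, the reporter and the sorting gate bear on them as well as the tissue. Across the 7 midbrain blocks of 96 wells, ependymal-like cells made up 47.0 to 66.7%, Sspo-high cells 26.8 to 51.8% and astrocyte-like cells 1.20 to 10.5%.

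**Figure D1:**
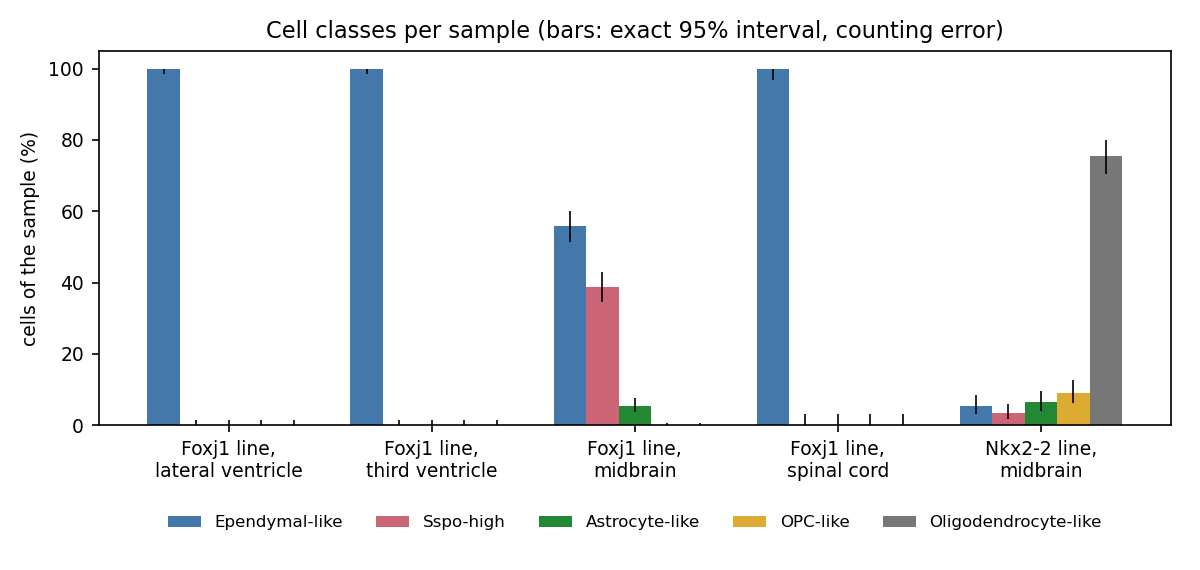
Percent of the sorted cells of each sample in each cell class, with exact 95% binomial intervals for counting error. The lateral ventricle, third-ventricle and spinal cord samples were 100% ependymal-like, the Foxj1 line midbrain sample was 55.8% ependymal-like and 38.8% Sspo-high, and the Nkx2-2 line midbrain sample was 75.5% oligodendrocyte-like.

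Third-ventricle and spinal cord cells lay largely in clusters of their own, while lateral ventricle and midbrain cells shared clusters 4, 5 and 8. Lateral ventricle cells lay in clusters 5 (130 cells), 6 (54), 8 (39), 4 (16) and 16 (1), and third-ventricle cells mainly in clusters 16 (182) and 15 (49). Midbrain ependymal-like cells lay in clusters 2 (131), 4 (79), 8 (37), 7 (36) and 5 (22). Spinal cord cells lay in cluster 17 (108), with 3 each in clusters 7 and 2. Cluster 6 led with genes that included Acta2, a smooth muscle actin, and cluster 17 with genes that included Stmn2, a neuronal tubulin regulator, beside Hox genes. With 1 sample per region, a cluster made mostly of 1 sample could not be told apart from that sample.

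The oligodendrocyte-like and precursor-like cells of the Nkx2-2 line carried factors of the oligodendrocyte lineage. Olig2, Sox10 and Mog were among the fixed markers used to name clusters, and Nkx2-2 drove the Cre that labelled the cells. Their presence was therefore set in part by the method and is a description only. Nkx2-2 (chromosome 2, 147177546 to 147194243, GRCm38), which drives oligodendrocyte differentiation, stood at 16.1 CPM in oligodendrocyte-like cells (95% interval 15.7 to 16.5). It was read in 40.5% of them, and stood at 45.7 CPM in precursor-like cells (43.3 to 48.2). Olig2, a determinant of this lineage, stood at 128 CPM in oligodendrocyte-like and 330 CPM in precursor-like cells, and Sox10 at 280 and 279 CPM. Sox9 was low in both, at 3.34 and 2.96 CPM, while Nfia stood at 129 and 362 CPM and Nfix at 163 and 218 CPM. Ddc, the decarboxylase of dopamine and serotonin synthesis, was read in 45.7% of oligodendrocyte-like cells at 98.1 CPM. Th, the rate-limiting enzyme of dopamine synthesis, had 0 reads in both classes. Spon1, a floor plate protein, reached 898 CPM in precursor-like cells against 1.49 CPM in oligodendrocyte-like cells. Mog, a myelin glycoprotein, stood at 3821 CPM in oligodendrocyte-like cells and was also read in 88.9% of the ependymal-like cells of this sample, at 2.99 CPM. In the ependymal-like cells of the Foxj1 line midbrain sample it was read in 1.64% of cells, at 0.0605 CPM. Reads of a few CPM in the Nkx2-2 line were therefore not taken as expression.

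The next comparison asked which genes set the ependymal-like cells of 1 region apart from every other region. Spinal cord cells carried Hox genes, which give position along the trunk. Hoxa7 (chromosome 6, 52214491 to 52221854) stood at 218 CPM (95% interval 215 to 221, 74.6% of cells) against 0.0806 CPM in the midbrain, the next region (2704-fold), where its 20 reads came from 1 cell. Hoxa9 stood at 122 CPM (120 to 124) against 0.0484 CPM, or 12 reads in 2 midbrain cells (2520-fold). Hoxb7 at 69.9 CPM and Hoxd8 at 59.3 CPM had 0 reads elsewhere and were at least 4214-fold and at least 3578-fold higher. Hoxc9 (chromosome 15, 102976439 to 102985099) stood at 72.8 CPM (71.1 to 74.5) against 0.0147 CPM, or 3 reads (0.00304 to 0.0430), in the third ventricle. Lin7a, a scaffold protein of cell junctions and synapses, was the remaining gene of the spinal cord, at 149 CPM against 0.878 CPM in the third ventricle (169-fold), all of it 179 reads of 1 cell. Without the cell with the most reads in each other region, Hoxa7 was at least 13111-fold, Hoxa9 6172-fold and Lin7a at least 8949-fold higher. The third ventricle was set apart by Gdpd2, a glycerophosphodiester phosphodiesterase (chromosome X, 100729873 to 100738895). It stood at 77.3 CPM (76.1 to 78.5) against 8.97 CPM in the midbrain (8.62-fold). Cuzd1 (chromosome 7, 131308554 to 131322292) stood at 131 CPM (130 to 133) against 15.6 CPM in the lateral ventricle (8.42-fold). The other genes of the third ventricle were Lhfp (134 against 26.5 CPM, 5.07-fold) and Nbl1, a secreted BMP antagonist (75.1 against 18.7 CPM, 4.01-fold). Some of the midbrain cells left out held more of these genes. Gdpd2 and Nbl1 stood at 141 and 393 CPM in cluster 1, and Cuzd1 and Lhfp at 83.5 and 164 CPM in cluster 0. The third-ventricle folds therefore hold against ependymal-like cells only. Rax, a factor of the tanycytes of this ventricle, had 0 reads in the third-ventricle sample. The blocks of each of the genes named by the rule did not overlap with those of any other region.

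No gene met the size rule for the lateral ventricle or the midbrain against the highest other region. At a fold of 2 the largest for the lateral ventricle were Larp1b (52.7 against 13.2 CPM) and Zic4 (3.28-fold), and for the midbrain Cnpy1 (3.89-fold) and Ifitm1 (2.92-fold). With minimums of 20 CPM and 10% of cells, the lateral ventricle was set apart by Dmrt3 (14.0-fold), Cyp4f15 (5.69-fold) and Emx1 (5.53-fold), of which Dmrt3 and Emx1 are factors of the developing cortex and Cyp4f15 is a cytochrome P450. The midbrain was then set apart by Irx2 (5.29-fold), a homeobox factor. Within the first sequencing project, which held all 4 regions, Cnpy1 met the rule for the midbrain (58.7 against 13.3 CPM, 4.40-fold), and without the requirement on blocks the transporter Slco1c1 met it for the lateral ventricle (4.19-fold).

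**Figure D2:**
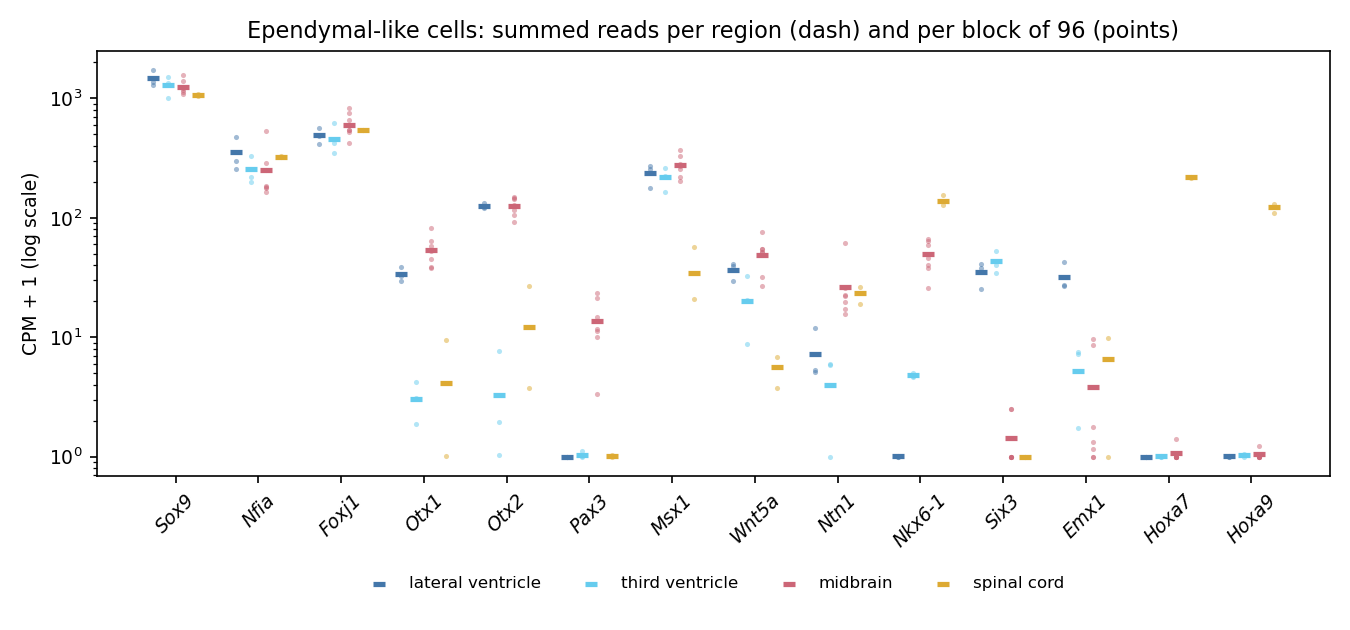
CPM + 1 on a log axis of 14 genes in the ependymal-like cells of the 4 Foxj1 line regions, where each dash is the sum over a region and each point a block of 96 wells. Hoxa7 and Hoxa9 stood at 218 and 122 CPM in the spinal cord and under 0.1 CPM elsewhere, while Sox9 lay between 1066 and 1480.3 CPM.

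The midbrain was then set against the mean of the other 3 regions, because dopamine progenitors arise in the ventral midbrain. Of 7 midbrain and isthmus patterning factors in the table, 3 reached 10 CPM in some region, and all 3 were at least 2-fold higher in the midbrain. Their median log2 ratio was 1.98, at percentile 100 of random lists and between 1.49 and 2.60 over the midbrain blocks. Pax3 (chromosome 1, 78101267 to 78197134), a factor of the dorsal neural tube, stood at 12.7 CPM in the midbrain (95% interval 12.2 to 13.1). It had 0 reads in the lateral ventricle, 8 in the third ventricle and 1 in the spinal cord. Otx1 stood at 52.9 CPM (52.0 to 53.8) against 32.9 CPM in the lateral ventricle, 2.02 CPM in the third ventricle and 3.14 CPM in the spinal cord. Otx2 (chromosome 14, 48657677 to 48673819), which specifies forebrain and midbrain, stood at 125 CPM in the midbrain and the lateral ventricle alike. It stood at 2.28 CPM in the third ventricle and 11.3 CPM in the spinal cord. Clusters 16 and 15, with most third-ventricle cells, held 0.0137 and 0 CPM of Otx2 and cluster 17, with 108 of 114 spinal cord cells, 0.0332 CPM, so these levels came from a few cells in other clusters. A read of Otx2 was found in 66.7% of lateral ventricle cells, 2.86% of third-ventricle cells, 63.0% of midbrain cells and 5.26% of spinal cord cells, and after thinning each cell to 20000 reads in 52.1, 2.04, 53.4 and 2.63%. Against the lateral ventricle alone the list's median log2 was 0.67, so the choice of reference set its size.

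Floor plate and dopamine progenitor genes had a median log2 ratio of 0.97 over the 4 of 9 members that reached 10 CPM (percentile 100, midbrain blocks 0.40 to 1.30), with 2 members at least 2-fold higher and 2 within 2-fold. Wnt5a (chromosome 14, 28504750 to 28527448), a Wnt ligand of dopamine neuron development, stood at 47.8 CPM in the midbrain. Its levels in the lateral ventricle, the third ventricle and the spinal cord were 35.8, 19.1 and 4.69 CPM. Ntn1 (chromosome 11, 68209364 to 68400823), the floor plate guidance cue netrin, stood at 25.4 CPM against 6.25, 3.02 and 22.7 CPM. Cluster 7, which led with Ntn1 among others, held 115 CPM, and without its cells the midbrain stood at 15.8 CPM, below the spinal cord. Msx1 (chromosome 5, 37820485 to 37824583), which acts in dopamine progenitors and in the dorsal midline, stood at 275 CPM against 238, 218 and 33.3 CPM. Spon1 stood at 3.18 CPM against 18.6 CPM in the third ventricle, and its log2 ratio of -0.95 rested on single blocks: it was 0.52 without third-ventricle block 2 (3.07 CPM) and -1.65 without midbrain block 5 (1.58 CPM). Against the highest other region the list's median log2 was 0.18, and without the spinal cord 0.52. Foxa1, a floor plate factor, stayed under 10 CPM and was read in 10.2% of midbrain cells and in 2.08%, 2.04% and 1.75% of cells of the lateral ventricle, the third ventricle and the spinal cord (thinned to 20000 reads, 7.87, 1.25, 1.22 and 1.75%). Clusters 15, 16 and 17, with most third-ventricle and spinal cord cells, held 0 CPM of Foxa1. Its reads in these regions therefore came from a few cells in other clusters. Of 6 dopamine neuron genes in the table, the 2 that reached 10 CPM went both ways (median log2 -0.32, percentile 45.1, and 0.18 from the deposited normalized values). Aldh1a1, a marker of a dopamine neuron subset, stood at 22.4 CPM (log2 1.77), and Ret, a growth factor receptor, had 0 reads in the midbrain against 12.8 CPM in the spinal cord, or 5.44 CPM without spinal cord block 1.

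Other positional factors also differed by region. The 16 of 19 Hox genes that reached 10 CPM were all highest in the spinal cord and at least 2-fold lower in the midbrain than the mean of the other regions (median log2 -3.38, percentile 0). Against the lateral or the third ventricle alone their median was 0.00. Forebrain patterning factors had a median of -1.22 (percentile 0.09), and -0.54 from the deposited normalized values, with 3 of 6 members at least 2-fold lower. Emx1 stood at 2.83 CPM (1.44 CPM without midbrain block 3) against 31.2 CPM in the lateral ventricle, and Pax6, a progenitor factor, at 19.1 CPM against 132 CPM in the spinal cord. Of 6 hypothalamic factors in the table, the 2 that reached 10 CPM were both lower (median -3.34, percentile 0.01). Six3, an anterior neural plate factor, stood at 0.443 CPM in the midbrain, at 34.0 CPM in the lateral ventricle and at 42.4 CPM in the third ventricle. With 0 reads of Six3 and Fezf1 in the spinal cord, the median against that region alone was 0.26. Ventral patterning and hedgehog response genes had a median of -0.16 over the 2 of 10 members that reached 10 CPM (percentile 33.5). Nkx6-1 (chromosome 5, 101658139 to 101664996), a ventral progenitor factor, stood at 48.5 CPM in the midbrain and 138 CPM in the spinal cord. It stood at 3.81 CPM in the third ventricle and had 1 read in the lateral ventricle (0.00553 CPM, interval 0.00014 to 0.0308). Gas1, a hedgehog co-receptor, stood at 9.26 CPM in the midbrain and 24.8 CPM in the spinal cord. Dorsal patterning genes had a median of -0.02 over 8 members (percentile 61.4), with 4 highest in the lateral ventricle and 0 in the spinal cord. Zic4, a dorsal zinc finger factor, stood at 173 CPM in the lateral ventricle, 52.6 CPM in the midbrain and 1.09 CPM in the spinal cord.

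The SOX and NFI factors, the subject of the series, were read in ependymal-like cells of all 4 regions, and all 10 stayed within 2-fold between the midbrain and the mean of the others. Sox9 (chromosome 11, 112782224 to 112787760) stood at 1245 CPM in the midbrain (95% interval 1241 to 1249, blocks 1091 to 1570). It stood at 1480.3 CPM in the lateral ventricle, 1296 CPM in the third ventricle and 1066 CPM in the spinal cord, and was read in 99.1 to 100% of cells. Nfia (chromosome 4, 97772734 to 98118874) stood at 251 CPM in the midbrain (249 to 253, blocks 163 to 534) and at 353, 254 and 323 CPM in the other 3 regions. Nfib was 98.2 CPM in the midbrain and 197 CPM in the spinal cord, Nfix 123 and 193 CPM, and Sox2, a stem cell factor, 48.6 and 102 CPM. Sox8 had the lowest ratio, at 5.68 CPM in the midbrain (log2 -0.83). The list's median log2 was -0.25, at percentile 1.22, with random lists between -0.21 and 0.22. Medians of single midbrain blocks ran from -0.61 to 0.17, so they took both signs, with a standard deviation of 0.251. The difference was thus about as large as that standard deviation. Leaving out 1 block at a time gave -0.39 to -0.17.

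Genes of motile cilia in the midbrain stayed close to the mean of the other regions. All 26 motile cilium components lay within 2-fold of that mean, 24 were above it and 15 were highest in the midbrain, with a median log2 of 0.20 (percentile 99.6). Medians of single midbrain blocks ran from -0.18 to 0.36, so they took both signs, with a standard deviation of 0.172. The difference was thus little larger than that standard deviation. Leaving out 1 block at a time gave 0.14 to 0.23. Rsph9, a radial spoke protein, stood at 703 CPM in the midbrain and at 563, 519 and 396 CPM in the lateral ventricle, the third ventricle and the spinal cord. Drc1, a dynein regulator, stood at 559 CPM against 411, 410 and 446 CPM. The 7 of 8 multiciliogenesis regulators that reached 10 CPM all stayed within 2-fold (median 0.08, percentile 69.8). Foxj1 (chromosome 11, 116330704 to 116335399), the master factor of motile cilia, stood at 595 CPM against 491, 460 and 543 CPM.

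Beyond the lists, 2 genes were higher and 3 lower in the midbrain by the size rule. Ifitm1 (chromosome 7, 140967221 to 140969825), an interferon-induced membrane protein, stood at 116 CPM against a mean of 25.5 CPM (4.54-fold). Cnpy1 (chromosome 5, 28200819 to 28245806), a regulator of FGF signalling at the midbrain-hindbrain boundary, stood at 51.9 against 11.5 CPM (4.53-fold). Cluster 7 alone held 212 CPM of Cnpy1, and its log2 was 1.63 without that cluster and 1.59 from the deposited normalized values, both under 4-fold. Lmo3, a LIM-domain transcription cofactor (chromosome 6, 138362918 to 138581968), was lower, at 8.78 against 86.3 CPM (9.83-fold). The spinal cord held 195 CPM of Lmo3, and without that region its log2 was -1.75. S1pr3, a sphingosine-1-phosphate receptor (chromosome 13, 51408639 to 51422797), stood at 24.4 against 125 CPM (5.11-fold). Aldoc, a glycolytic enzyme of astrocytes (chromosome 11, 78322968 to 78327781), stood at 55.6 against 229 CPM (4.12-fold). Among the midbrain cells left out, Aldoc stood at 1149 CPM in cluster 1 and 141 CPM in cluster 0, and Lmo3 at 69.2 CPM in cluster 0. S1pr3 stood at 11.2 and 0.369 CPM in clusters 1 and 0. The lower levels of Aldoc and Lmo3 therefore hold for ependymal-like midbrain cells only. Leaving out 1 block at a time gave log2 ratios of 1.63 to 2.43 for Cnpy1, 1.91 to 2.29 for Ifitm1 and -2.15 to -1.90 for Aldoc, so these 3 genes passed under 4-fold in some of these settings.

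Glial and BMP genes were lower in part. Radial glia and stem cell genes had a median of -0.16 (percentile 4.88), with 2 of 13 members at least 2-fold lower. These were Gfap, the astrocyte intermediate filament, at 32.2 CPM against 89.9, 136 and 96.0 CPM in the lateral ventricle, the third ventricle and the spinal cord, and Id3 (log2 -1.44). The other regions entered whole, while the astrocyte-like midbrain cells, with Gfap at 4924 CPM, were left out. The lower level therefore holds for ependymal-like midbrain cells and not for the midbrain sample. Channels, transporters and junctions had a median of 0.01 (percentile 46.3) with 11 of 12 members within 2-fold. The exception, the glutamate transporter Slc1a3, stood at 135 CPM in the midbrain and at 288, 621 and 448 CPM elsewhere. In the astrocyte-like midbrain cells that were left out it stood at 3007 CPM. BMP pathway genes had a median of -1.10 (percentile 0.11, midbrain blocks -2.24 to -0.11), with 4 of 6 members at least 2-fold lower. Id2, a BMP target, stood at 69.2 CPM against 186, 174 and 115 CPM. The BMP median was 0.64 against the spinal cord alone and -0.14 from the deposited normalized values.

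The remaining lists differed less or rested on the spinal cord. Wnt pathway genes had a median log2 of -0.19 (percentile 15.3), with 1 of 8 members lower, the Wnt antagonist Sfrp5 (log2 -1.18). Guidance and secreted cues had a median of -0.47 (percentile 2.84), with the ephrin receptor Epha7 higher (log2 1.54) and 3 members lower, such as Robo2 (log2 -1.27). Interferon and antigen presentation genes had a median of 0.40 (percentile 99.8, blocks -0.51 to 0.98) with all 9 members within 2-fold. Among them were H2-D1 (log2 0.69) and Ifitm3 (log2 -0.83, with 2449 CPM in the spinal cord). Immediate early and dissociation response genes, which respond to tissue dissociation, had a median of 0.31 (percentile 99.9, blocks -0.13 to 0.92), and 11 of 15 were highest in the spinal cord. Fos stood at 788 CPM in the lateral ventricle, 1498 CPM in the third ventricle, 2319 CPM in the midbrain and 3485 CPM in the spinal cord. Hspa1a, a heat shock gene, was higher in the midbrain (log2 1.65). Against the spinal cord alone the median of this list was -0.41. The 4 of 7 cell cycle genes that reached 10 CPM were all highest in the spinal cord (median -0.85, percentile 3.32), with Top2a at 12.3 CPM there and 0.855 CPM in the midbrain. Without spinal cord block 1 that median was 0.37 and Top2a stood at 0.0579 CPM in the spinal cord.

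The sex-linked genes differed between samples as well. Xist, read from the inactive X chromosome of females, stood at 35.6 CPM in the lateral ventricle, 38.3 CPM in the third ventricle, 70.3 CPM in the midbrain and 3.74 CPM in the spinal cord. In the Nkx2-2 line, which came from females only, it stood at 183 CPM. The Y-linked Ddx3y stood at 14.9, 16.7, 29.5 and 62.8 CPM in the 4 Foxj1 line samples and had 4 reads (0.00928 CPM) in the Nkx2-2 line. Blocks of 1 sample also differed, with Xist at 148 CPM in midbrain block 1 and 0.0269 CPM in block 3, so the spread between blocks held differences between animals. Both spinal cord blocks held little Xist (5.63 and 0.463 CPM) and more of the Y-linked Eif2s3y (79.8 and 80.1 CPM). Region and make-up by sex could therefore not be told apart for the spinal cord, which also enters the mean of the other regions.

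**Figure D3:**
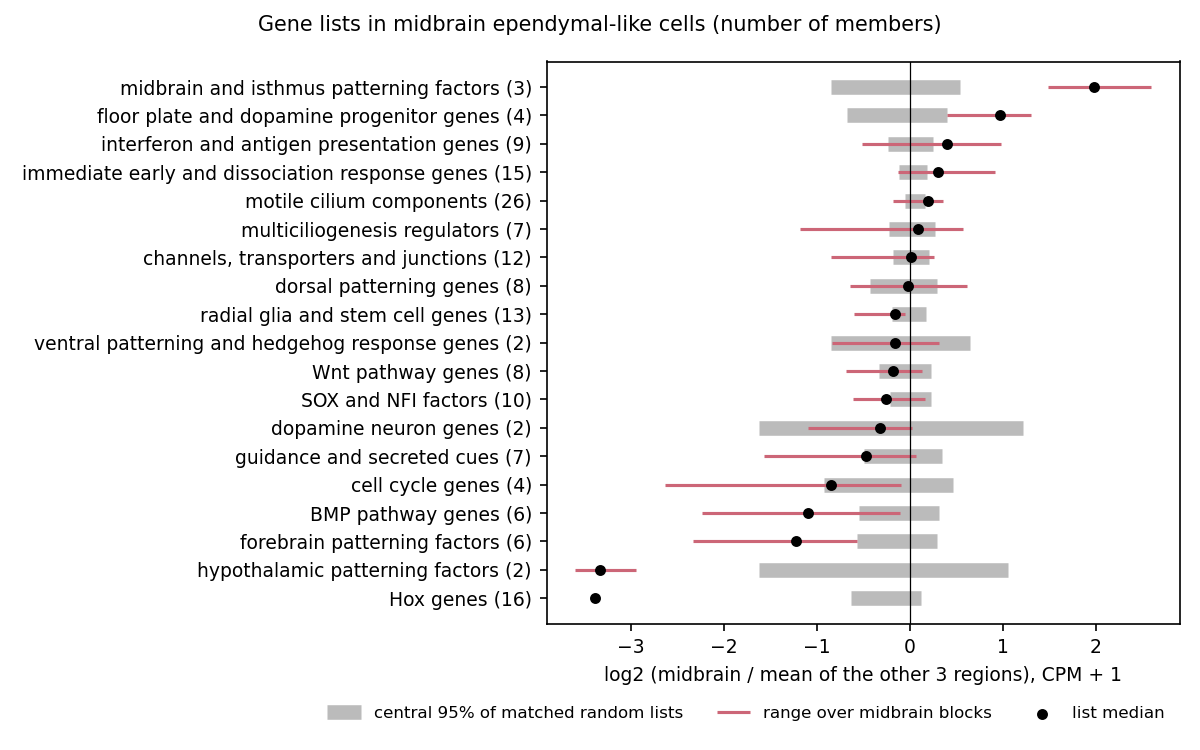
Median log2 ratio of each of 19 gene lists, midbrain over the mean of the other 3 regions in ependymal-like cells (dot), with the range over midbrain blocks of 96 wells (line) and the central 95% of 10000 random lists matched on expression (grey). Midbrain and isthmus factors (1.98) and floor plate genes (0.97) lay to the right of their random lists, and Hox genes (-3.38) and hypothalamic factors (-3.34) to the left.

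The last comparison asked how midbrain cells of the 2 Cre lines differed within a class. Among the classes, astrocyte-like cells alone reached 20 cells in both samples. The 21 cells of the Nkx2-2 line were all in cluster 14, which led with Cldn10, Gjb6 and Ntsr2. Of the 30 cells of the Foxj1 line, 29 were in cluster 1, which led with Prokr2, Gfap and Chrna3, so clusters and lines were nearly the same split. Motile cilium components were lower in the Nkx2-2 line, with 23 of 24 members at least 2-fold lower and a median log2 of -5.58 (percentile 0). Ak7, an adenylate kinase of cilia, had 1 read (0.0709 CPM) against 131 CPM. Markers of ependymal cells went the same way, with Rarres2 at 62.7 against 349 CPM and Tekt1 at 60.3 against 336 CPM, and cluster 1 had 1 astrocyte marker and 1 marker of another class among its 10 leading genes. All 4 multiciliogenesis regulators were lower (median -4.43, percentile 0.87), with Foxj1 at 2 reads against 46.3 CPM. Dorsal patterning genes were lower in 6 of 7 members (median -4.36, percentile 0.145), with Gdf10, a BMP-family ligand, at 0 reads against 417 CPM. Ventral patterning and hedgehog response genes were higher in 6 of 7 members (median 2.38, percentile 99.8). Olig2 stood at 115 against 8.39 CPM, Nkx6-2 at 106 CPM against 0 reads, and Nkx2-2 at 16.5 CPM against 1 read. Foxj1 and Nkx2-2 drove the Cre that labelled the cells of the 2 lines. Differences in these 2 genes, and in the cilium genes that go with Foxj1, could therefore come from the labelling itself. Immediate early genes were higher in 10 of 12 members (median 4.14, percentile 100), with Fos at 3758 against 118 CPM and Egr1 at 964 against 7.22 CPM. From the deposited normalized values the median of the motile cilium list was -2.01.

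SOX and NFI factors in these astrocyte-like cells had a median of 0.14 (percentile 73.2), with members going both ways. Sox9 stood at 946 CPM in the Nkx2-2 line and 1113 CPM in the Foxj1 line, and Nfia at 441 and 285 CPM. Sox5 was higher, at 140 and 20.9 CPM, and Nfix lower, at 3.33 and 172 CPM. Radial glia genes had a median of -1.20 (percentile 2.61), with Vim, an intermediate filament, at 2.06 against 2222 CPM and Gfap at 274 against 4924 CPM. Hes5, a Notch target in the same list, stood at 1017 against 23.4 CPM. Channels, transporters and junctions had a median of 0.87 (percentile 97.7), with the gap junction protein Gja1 at 5012 against 1657 CPM. BMP pathway genes had a median of 1.17 (percentile 95.1), with Id2 at 2122 against 257 CPM. The other lists had medians of -4.72 for guidance cues (percentile 0), -2.02 for midbrain and isthmus factors (percentile 23.6) and -1.55 for Wnt genes (percentile 17.4). Interferon genes had a median of -0.20 (percentile 62.1) and forebrain factors of 1.15 (percentile 91.3). Floor plate genes had a median of -3.21 (percentile 1.58), though Spon1 was higher at 572 against 47.8 CPM. Against the 9 Foxj1 line cells of the second sequencing project alone, which also held the Nkx2-2 line, several medians differed. They were -0.32 for radial glia genes, 0 for Wnt genes, 2.58 for BMP genes, 3.91 for ventral genes and 5.78 for immediate early genes. Floor plate genes stood at -2.34, forebrain factors at 1.90, interferon genes at 0.38 and SOX and NFI factors at 0.61.

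By the size rule, Kcnk1, a potassium channel (chromosome 8, 125995170 to 126030685), led the genes higher in the Nkx2-2 line astrocyte-like cells. It stood at 694 CPM (95% interval 680 to 708) against 0.0556 CPM (1 read, 0.00141 to 0.310). Dusp6, a feedback inhibitor of ERK signalling, stood at 322 CPM against 2 reads. Cadm2, Pantr1, Rgcc, Olfr287, Faim2 and Parm1 stood at 58.3 to 167 CPM against 1 read each. Abtb2 and the Wnt receptor Fzd2 had 0 reads in the Foxj1 line and were at least 936-fold and at least 923-fold higher. Anxa2, a membrane-binding annexin (chromosome 9, 69453620 to 69491795), was lower, at 0.425 CPM (6 reads, 0.156 to 0.926) against 1669 CPM, or 1011 CPM in the second project. Pamr1 had 0 reads against 584 CPM, or 208 CPM in the second project, and was at least 2745-fold lower than in both projects together. Armh4 stood at 2 reads against 528 CPM (433 CPM in the second project), and Rit2, Lrrc23, Myadm, Cfap45, Smoc1, Ecm2 and Iqck at 1 read each against 162 to 252 CPM (121 to 200 CPM in the second project). No block held 10 of these cells in either sample, so no spread between blocks could be set beside these values. In the second sequencing project, which held the Nkx2-2 line, 9 Foxj1 line cells remained, and against these the median of the motile cilium list was -4.02.

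With a class minimum of 10 cells, added after the data were seen, the 18 ependymal-like cells of the Nkx2-2 line could be set against the 305 of the Foxj1 line. Of the 18, 17 were in cluster 4 and 1 in cluster 2. Motile cilium components then had a median log2 of -0.14 (percentile 1.49) and SOX and NFI factors 0.26 (percentile 80.7). Immediate early genes had a median of 0.44 (percentile 99.5) with 6 members higher and 4 lower. Cluster 4 held 79 of the 305 Foxj1 line cells and cluster 2 held 131, and Fos stood at 5806 CPM in cluster 4 and 79.2 CPM in cluster 2. Errfi1, a feedback inhibitor of EGF receptor signalling, was higher at 149 against 3.97 CPM (37.4-fold), as was the kinase Plk2 at 229 against 11.9 CPM (19.3-fold). In the second project alone the Foxj1 line stood at 1.87 CPM of Errfi1 and 5.79 CPM of Plk2. Nr4a1, an immediate early gene, stood at 656 against 64.9 CPM (10.1-fold). Tox2, an HMG-box factor, had 0 reads against 89.4 CPM (at least 569-fold lower). For 11 Sspo-high cells of the Nkx2-2 line against 212 of the Foxj1 line, 12 of 15 immediate early genes were lower (median -2.70, percentile 0). Of the 11 cells 10 were in cluster 9, where Fos stood at 149 CPM, and of the 212 cells 180 were in cluster 0, where it stood at 11048 CPM. Hmox1, a heme oxygenase induced by oxidative stress, stood at 222 against 14.1 CPM (15.7-fold). No block held 10 of the Nkx2-2 line cells of these 2 classes, so blocks could not be compared.

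**Figure D4:**
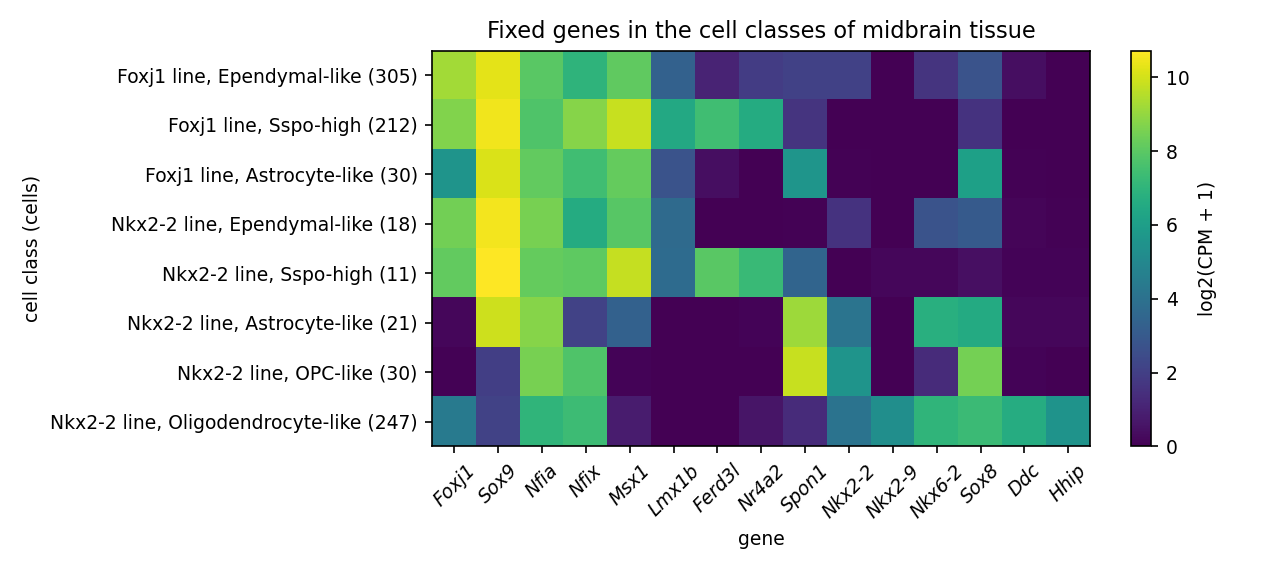
Log2(CPM + 1) of 15 genes in 8 combinations of midbrain sample and cell class, by colour. Sox9 stood at 1245 CPM in Foxj1 line ependymal-like cells and 3.34 CPM in Nkx2-2 line oligodendrocyte-like cells, while Nfia stood at 251 and 129 CPM.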

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

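All of these values came to attention only after the tables were seen, and no test of their source was run. The count table held reads for Egfp, the gene of a green fluorescent protein, which took part in no comparison, and the labels named tdTomato, a red protein, as the reporter of the Foxj1 line. Reads of Egfp lay above the level that a count of 0 allows in all 5 samples. They stood at 41.0 CPM in the lateral ventricle (95% interval 40.1 to 41.9, 65.0% of cells) against a limit of 0.0166 CPM. The third ventricle held 20.3 CPM (19.7 to 20.98, 49.0% of cells) against 0.0147 CPM, and the Foxj1 line midbrain 115 CPM (114 to 116, 83.4% of cells) against 0.00682 CPM. The spinal cord held 45.2 CPM (43.9 to 46.6, 58.8% of cells) against 0.0317 CPM, and the Nkx2-2 line midbrain 9.62 CPM (9.33 to 9.92, 39.4% of cells) against 0.00696 CPM.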

How the results depend on the processing

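The 5 alternatives added after the data were seen were the lateral ventricle without cluster 6, the midbrain without cluster 7, the other regions without the spinal cord, Sspo-high cells counted as ependymal-like, and a class minimum of 10 cells. No paired analysis was possible because each group held 1 sample and the values came from no test. Using all deposited cells gave the reported values, since the filter removed none, and this says nothing about stability. Its values are still counted as stayed in the tallies of shares, list medians and single genes below, which therefore overstate stability. The stricter filter kept 1469 of 1473 cells, so it tested little as well. Counting Sspo-high cells as ependymal-like put that share at 94.5% in the Foxj1 line midbrain and 8.87% in the Nkx2-2 line by construction, and the other 43 values of ependymal-like shares stayed within their counting intervals. The spread between blocks was here the standard deviation of the medians of single midbrain blocks. For the midbrain against the other regions, the medians of the 4 main lists (midbrain and isthmus, floor plate, SOX and NFI, motile cilium) stayed within the spread between blocks in 70 values under alternatives and moved beyond it in 10. For the other lists 225 values stayed within it or within 0.005, 66 moved and 5 reversed, where a reversal was counted only for lists outside the range of random lists. Another 28 values of 7 lists inside that range, counted as stayed or moved, turned sign, such as dopamine neuron genes with 0.18 from the deposited normalized values and 0.67 without the spinal cord. Hox genes had no spread between midbrain blocks, so for them any larger change counted as moved. The midbrain and isthmus median was 0.67 against the lateral ventricle, 4.16 against the third ventricle, 3.70 against the spinal cord, 0.67 against the highest other region, 1.55 without the spinal cord and 1.27 with a pseudocount of 10 CPM. The floor plate median was 1.60 against the spinal cord, 0.18 against the highest other region and 0.52 without the spinal cord, and the SOX and NFI median -0.57 against the highest other region. Signs reversed against the spinal cord alone for hypothalamic factors (0.26), BMP genes (0.64) and immediate early genes (-0.41), and against the highest other region for immediate early genes (-0.41) and interferon genes (-0.20). Leaving out 1 block at a time gave 1.80 to 2.09 for midbrain and isthmus factors, 0.78 to 1.04 for floor plate genes, -0.39 to -0.17 for SOX and NFI factors and 0.14 to 0.23 for motile cilium components. Cell cycle genes ran from -1.14 to 0.37. Within classes of the 2 Cre lines, the cilium median of astrocyte-like cells was -4.02 in the second project only and -2.01 from the deposited normalized values, whose means of log values draw low genes together, and the BMP median of Sspo-high cells turned to 0.13 from those values. For the other list medians, a value counted as stayed if it lay near the reported one, within a set fraction of the width of the random range. By this, 263 values stayed and 44 moved. Another 26 values of 14 medians inside the random range, counted as stayed or moved, turned sign. For single genes named between the lines, 250 values stayed within counting intervals and 170 moved. The cause of these changes was not tested. Of the 4 genes named for the third ventricle, 2 were kept at minimums of 100 CPM and 50% of cells, as were 2 of 6 for the spinal cord. Depth limited shares of cells more than sums: with each cell thinned to 20000 reads, Nfia was read in 83.3% of midbrain cells in place of 96.7%, and Sox9 in 99.0%.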

Other observations

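The comparison of Sspo-high with ependymal-like cells, and for the patterns weighed here the tests on the sequencing project, on sex and on doublets, were chosen only after the results were seen. Within the Foxj1 line midbrain sample, the 212 Sspo-high cells differed from the 305 ependymal-like cells in several lists, among them dorsal patterning and BMP pathway genes. Dorsal patterning genes had a median log2 ratio of 1.98 (percentile 99.97 of random lists), with 5 of 7 members at least 2-fold higher and 0 lower, such as Zic4 at 446 against 52.6 CPM. BMP pathway genes had a median of 2.59 (4 of 5 higher), guidance cues 2.84 (5 of 6 higher), midbrain and isthmus factors 2.02 (3 of 3 higher) and forebrain factors 1.70 (2 of 3 higher). Floor plate and dopamine progenitor genes had a median of 1.74, with 4 members higher and 2 lower. Msx1 stood at 907 against 275 CPM, Lmx1b, a midline and dopamine progenitor factor, at 88.0 against 9.11 CPM, and Ferd3l, a basic helix-loop-helix factor of the ventral midbrain, at 171 against 1.10 CPM. Nr4a2, a factor of dopamine neurons and of the same family as the immediate early gene Nr4a1, stood at 94.4 against 2.77 CPM. Immediate early genes were also higher in these cells (median 2.37), so the level of Nr4a2 was not taken as a sign of dopamine progenitors.

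In Sspo-high cells the SOX and NFI factors stood at similar levels as a list, and motile cilium components were lower. SOX and NFI factors had a median of -0.24 (percentile 19.3), with Sox9 at 1444 against 1245 CPM and Nfix at 436 against 123 CPM. Foxj1 stood at 413 against 595 CPM, and multiciliogenesis regulators had a median of -0.53 (percentile 7.04, 2 of 7 lower). Motile cilium components had a median of -0.85 (percentile 0.09) with 8 of 26 members at least 2-fold lower, channels, transporters and junctions -0.98 with 6 of 12 lower and 3 higher, and interferon genes -1.60 with 7 of 9 lower. Radial glia genes had a median of 1.26 (percentile 99.95, 7 of 13 higher and 2 lower). Wnt genes (0.64, percentile 88.3, 2 of 7 higher and 3 lower) and cell cycle genes (0.32, percentile 54.1) lay inside the range of random lists. Immediate early genes had a median of 2.37 with 13 of 15 higher, some of which, such as Fosb and Atf3, also led the Sspo-high clusters. In the Nkx2-2 line, Foxj1 was read in 38.1% of oligodendrocyte-like cells, at 20.4 CPM.

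The Sspo-high cells of the midbrain sample (Sspo, chromosome 6, 48448229 to 48501250) raised the question of what they were. Doublets of an ependymal-like cell and another cell would keep much of the ependymal markers, but the median ratio of the 5 most abundant was 0.0848, with Tmem212 at 0.0734 and Rarres2 at 0.0120, though Rsph1 stood at 0.660 and Dynlrb2 at 0.484. A difference between sequencing projects was argued against by a share of 35.2% (95% interval 27.4 to 43.5) in the second and 40.0% (35.2 to 45.02) in the first. Car3, a gene of the subcommissural organ that took no part in naming clusters, was 30.5-fold higher, at 750 against 24.6 CPM. As a hypothesis found and tested on the same data, these cells may come from the subcommissural organ, a gland that secretes SCO-spondin.

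Midbrain block 6 stood apart from the other midbrain blocks, with 32.8% of genes at least 2-fold off against 11.6 to 18.7%. The sequencing project was argued against by 13.4% in block 7 of the same project, and fewer reads per cell by 18.1% of genes of at least 100 CPM after thinning, with the other blocks at 0.709 to 2.51%. Sex was argued against by blocks 3 and 4, which like block 6 held more of the Y-linked Eif2s3y than Xist but had 13.6 and 14.4% of genes 2-fold off. On the dissected tissue the values went both ways, since 14 of the 47 cells (29.8%) lay in cluster 5 with 130 lateral ventricle cells, while Emx1, at 31.2 CPM in the lateral ventricle, had 0 CPM in the block, and Pax3, at 0 CPM in the lateral ventricle, had 22.5 CPM, the highest of all midbrain blocks. Tissue, other differences between animals and library quality stayed open, since block 6 had the fewest detected genes (median 3946 against 4573 to 5445.5), as had lateral ventricle block 2 and third-ventricle block 3 among theirs, with 22.2 and 14.5% of genes 2-fold off.

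Foxa1 (chromosome 12, 57540628 to 57546916) had at least 5 reads in 29 of the 305 midbrain ependymal-like cells, from all 7 blocks, and 15 of them were among the 36 midbrain cells of cluster 7. That cluster led with Foxa1, Ntn1 and En1 among others, so the overlap is a description only. Higher depth was argued against by a ratio of median reads of 0.927 to the other cells. By overlap of intervals, the criterion used, a ventral position could not be told apart from another one. At least 5 reads of Pax3 or Pax7, genes of the dorsal midbrain, were found in 0 of 29 cells (0%, interval 0 to 11.9). Of 276 others 12.7% had them (8.99 to 17.2), and these intervals overlapped. The intervals cover counting error over cells, and their overlap does not show that the percents were alike. En1, an isthmus factor, was found in 31.0% of the Foxa1 cells (15.3 to 50.8) and 5.80% of the others (3.35 to 9.24). Intervals overlapped for Lmx1a (13.8 and 1.81%), Ntn1 (31.0 and 12.3%), Nkx6-1 (37.9 and 18.8%), Zic1 (0 and 13.8%), Otx2 (44.8 and 58.0%), Msx1 (86.2 and 80.8%), Spon1 (3.45 and 1.45%) and Lmx1b, which was lower in the Foxa1 cells (6.90 and 9.06%).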
